A study of Mus musculus with 12 samples.

How the data were processed

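RNA sequencing libraries were made from 12 wells of C2C12 cells, 6 of the ChR2::tdTomato line (ChR2) and 6 of the wild-type line. Per the labels' protocols, cells were seeded on a fibrin gel 1 mm thick with 8 mg of fibrinogen per mL, kept for 2 days in growth medium with aminocaproic acid and then for 6 days in differentiation medium with horse serum, aminocaproic acid and IGF-1. RNA was selected by its poly(A) tail. Libraries were amplified with 14 PCR cycles and read as pairs of 50 bases. The protocol adds that samples with little RNA went through ribosomal RNA depletion, without naming them. Groups were taken from the genotype label, and replicate numbers from the sample titles.

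The authors deposited a table of estimated counts per gene, whose values need not be whole, and a table of TPM for the same 56941 genes and 12 libraries. The submitters' processing notes list BWA 0.7.12-r1039, bedtools 2.25.0, STAR and Salmon, and the builds mm10, hg19 and GRCm39. The role of each tool and build is not given in the sources used here, and no coordinates are printed. Gene symbols were taken from the deposited tables, which pair them with Ensembl identifiers. Columns of per-sample values left unused numbered 0. A few symbols belong to 2 identifiers, among them Aldoa, whose named row is the lowly expressed one. A level of that row is therefore given only for a well that lay far from the rest of its line.

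The estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 13168, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16 in R 4.3.3), with genotype as the term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Levels are CPM on TMM-scaled library sizes. A count of 3 in a library was taken as the floor of detection. Counts come from amplified reads without molecular identifiers, so depth bounds counting error only, and it was lowest in wild-type wells 2 and 5.

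Gene lists numbered 34 and were fixed before the data were examined, as were the design, the other settings to be tried and the rule for named genes. They were tested by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 as the main test, with an estimated correlation, and by fry; lists with fewer than 3 tested members were left out. Named genes were the 10 largest rises and 10 largest falls, and the 5 smallest p in each direction, among called genes with no overlap between the lines, at least 5 CPM in the higher line and an established symbol; up to 2 rises and 2 falls per list among called members of at least 1 CPM, or the 2 most abundant members where none was called; and 15 genes named beforehand. This gave 126 genes, of which the most relevant are described. Single results of some of them are not reported here, and all remain in the counts.

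Tested on simulated counts for the 12 libraries (13051 genes), the fit recovered 27.7% of 1.5-fold, 68.7% of 2-fold and 96.9% of 4-fold changes, and 2.31% of its calls were false. For the 10 libraries without wild-type wells 2 and 5 (13342 genes) it recovered 47.0%, 83.3% and 98.4%, and 8.64% of its calls were false. The simulations changed only 197 and 195 of these genes. They also drew all libraries from 1 common profile, so wild-type wells 2 and 5 differed from the others in depth only. The rates may differ for the real data, which depart from both settings.

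Same-line libraries were checked for repeated deposits of 1 library by a chi-square statistic over genes with at least 10 counts in a pair. The lowest value per degree of freedom was 5.09, so no pair agreed within sampling noise and each library counted once.

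Other settings chosen before the data were examined were DESeq2's size factors and upper-quartile scaling in place of TMM, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no filter, a filter of at least 1 CPM in at least 6 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1) with a filter of 1 TPM in 6 libraries and on log2(TPM + 1) without it, a test against a 1.5-fold change, the replicate number as a block, and each library left out. Chosen after the data were seen were the fits without wild-type wells 2 and 5, without those and ChR2 well 4, with a covariate for wild-type wells 2 and 5, with RNAs lacking a poly(A) tail removed first, with at least 5 CPM in 6 libraries, and on log2(TPM + 1) in the 10 libraries. Chance groupings were examined by 100 seeded divisions of the libraries into groups of the same sizes. Figures were drawn with matplotlib 3.10.9.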

Results

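RNA was sequenced from C2C12 cells, a mouse myoblast line that fuses into multinucleated myotubes in differentiation medium, grown as sheets on a fibrin gel. The series design sets an optogenetic line, which carries the light-gated cation channel ChR2 fused to the red fluorescent protein tdTomato, against the wild-type line under identical culture. Each line filled 6 wells, and each well gave 1 library. The labels mention no light stimulation for these wells. Total estimated counts ran from 7388730 to 12229400 in the ChR2 libraries. In the wild-type libraries they ran from 10268000 to 13628500 in wells 1, 3, 4 and 6, with 1061050 in well 2 and 2809670 in well 5. No label says that the wells of a line came from separate cultures, so p-values measure only the spread between wells, and any difference belongs to these lines with their histories as well as to the transgene. The transgene itself was not analysed here.

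Wild-type wells 2 and 5 stood apart from the other 10 libraries in the kinds of RNA they held. The 7SL RNA, the RNA core of the signal recognition particle and a transcript without a poly(A) tail, took 24.8% of the counts in well 2 and 8.37% in well 5, against at most 0.0341% in any other library. Replication-dependent histone transcripts, which also lack a tail, took 0.301% and 0.278%, against at most 0.0531% elsewhere. Mitochondrially encoded messages took 0.0843% and 0.211% in wells 2 and 5 and between 0.670% and 4.02% elsewhere. Across genes, the median Pearson correlation of log2 CPM was 0.981 between ChR2 wells, 0.919 between wild-type wells and 0.970 between the 4 remaining wild-type wells. Between the lines it was 0.940, or 0.948 without the same pair of wells. The extraction protocol states that low-input samples were prepared by ribosomal RNA depletion and does not name them, and both of these wells are wild type. The counts of changed genes are therefore given also without them, as are the counts of lists whose balance of higher and lower calls turned. Other list counts are over all 12 libraries unless stated. The 4 remaining wild-type wells also differed among themselves. On the first principal component of log2 CPM in the 10 libraries (47.2% of the variance), wells 1 and 3 lay at 62.0 and 51.3. Wells 4 and 6 lay at 23.5 and 24.3, and the ChR2 wells between -29.6 and -23.0. The median correlation of wells 4 and 6 was 0.962 and 0.958 with ChR2 wells. With their own line, wells 2 and 5 included, it was 0.957 and 0.956.

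**Figure D1:**
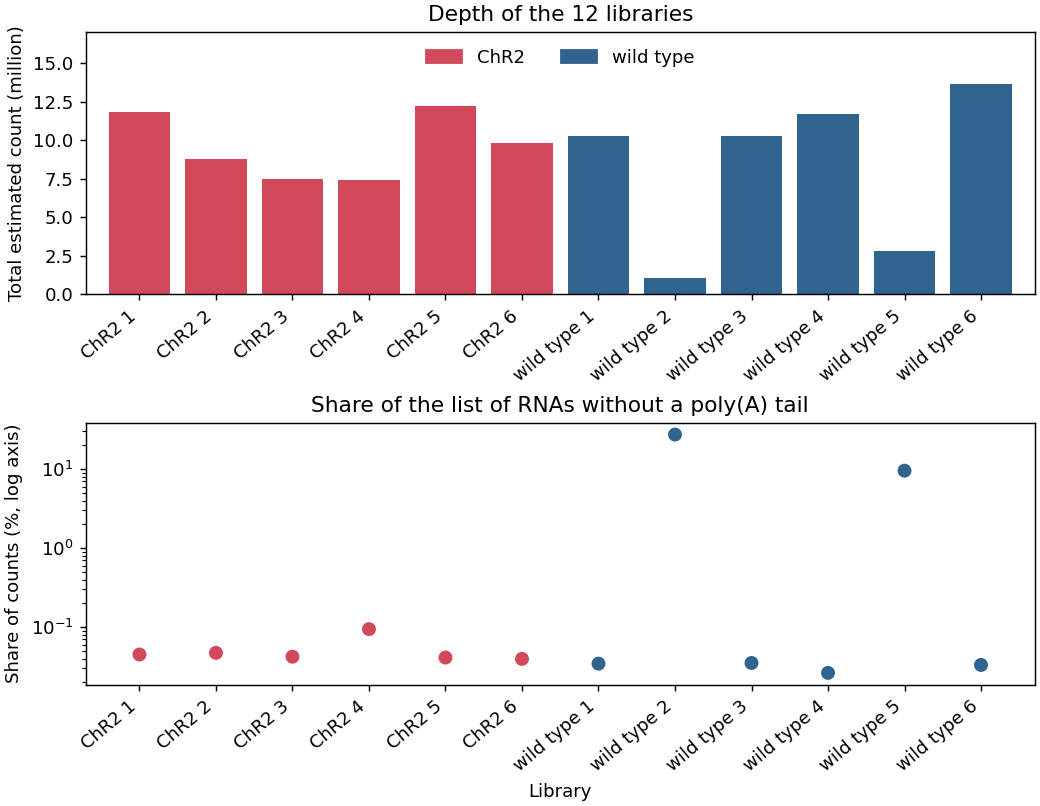
Upper panel: total estimated count of each library, ChR2 wells in red and wild-type wells in blue. Lower panel: share of counts in the list of RNAs without a poly(A) tail, in percent on a log axis; wild-type wells 2 and 5 lie at 27.4% and 9.57%, and the other 10 libraries between 0.0264% and 0.0945%.

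The comparison asked how the ChR2 line differs from the wild-type line after 6 days of differentiation. ChR2 wells held more message of the cell cycle genes Ube2c and Mki67, of the matrix genes Fmod and Col14a1 and of the secreted factors Bdnf, Cxcl12 and Apln. They held less of the myogenic factor Myog and of the postsynaptic kinase Musk. Of 13168 genes tested, 3701 (28.1%) changed, 1838 higher and 1863 lower in ChR2 wells (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Changes of at least 2-fold were found for 956 genes, 663 higher and 293 lower. Without wild-type wells 2 and 5, 4749 of 13484 genes changed, 2545 higher and 2204 lower, and 3334 of the 3701 genes were called again in the same direction. No overlap between the 6 wells of each line was seen for 1987 genes (15.1%), where chance gives 0.216%. All levels below are CPM as mean ± SD over n = 6 wells of each line, and log2 fold changes are ChR2 over wild type.

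Several genes were close to silent in 1 of the lines. Cdhr1 (ENSMUSG00000021803), a cadherin-related gene best known from photoreceptors, stood at 19.9 ± 1.40 CPM in ChR2 and 1.07 ± 0.37 CPM in wild-type wells (log2 fold change 4.20, SE 0.20, adjusted p = 1.54e-08). Nxf3 (ENSMUSG00000057000), of the nuclear RNA export factor family, stood at 22.2 ± 2.18 and 1.6 ± 0.50 CPM (log2 fold change 3.67, SE 0.18, adjusted p = 1.57e-08). Cilp, a cartilage matrix protein gene, was at 14.0 ± 2.75 against 0.34 ± 0.32 CPM, and Pde3a, a cyclic nucleotide phosphodiesterase gene, at 6.31 ± 1.06 against 0.098 ± 0.12 CPM. The other large rises by the rule for named genes were Arap2 (log2 fold change 3.68), Dcaf8l (3.54), Unc5c, which encodes a netrin receptor (3.43), Sprr1a (3.31), Gpr15lg (3.15) and Thsd7a (3.11). In the opposite direction, Cdh11, the mesenchymal cadherin, was at 2.37 ± 0.80 CPM in ChR2 and 28.5 ± 15.5 CPM in wild-type wells (log2 fold change -3.62, SE 0.35, adjusted p = 1.63e-05). The kainate receptor gene Grik3 fell by 3.78 on the log2 scale, Spats2l by 3.24 and Rab29 by 2.99. Acot6, Gprc5c and Galnt6 were among the 5 falls with the smallest p, at log2 fold changes of -2.10, -1.69 and -1.49.

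Among the remaining largest falls by the rule for named genes, Gsta1 stood at 1.41 ± 0.44 CPM in ChR2 and 99.6 ± 86.6 CPM in wild-type wells (log2 fold change -6.03, SE 0.92, adjusted p = 0.00093). Gsta4 (-3.14), Gstp2 (-2.91), the quinone reductase Nqo1 (-3.29) and the aldehyde dehydrogenase Aldh3a1 (-4.01) fell too, as did the cytokine gene Il1b (-2.37). The wild-type wells were far apart: the SD of Nqo1 was 54.6 CPM around a mean of 72.1 CPM, against 1.02 around 7.44 CPM in ChR2. Wild-type wells 4 and 6 lay closest to the ChR2 wells, at 20.2 and 12.3 CPM of Nqo1 and 5.23 and 13.6 CPM of Gsta1. Gsta1 and Gstp2 have near-identical paralogs, so how reads were divided among them is uncertain.

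Cell cycle genes rose as a group. Of 36 tested members of that list, 31 were higher in ChR2 wells, with a median log2 fold change of 1.37 over the list. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was at 63.7 ± 5.27 against 14.7 ± 6.98 CPM, Ccnb2, a mitotic cyclin, at 43.7 ± 4.06 against 11 ± 6.11 CPM, and the proliferation marker Mki67 at 161 ± 37.9 against 50.6 ± 34.9 CPM. Camera called the list higher (adjusted p = 2.43e-17 with a preset correlation, adjusted p = 0.258 with an estimated correlation). Of 15 regulators of myoblasts and progenitors, 8 rose and 2 fell. Id2, an inhibitor of myogenic helix-loop-helix factors, was at 53.3 ± 5.93 against 24.2 ± 9.66 CPM, while Heyl and Spry1 fell by 1.15 and 0.85 on the log2 scale. That list had an adjusted p of 0.0478 by camera, and an adjusted p = 0.603 with an estimated correlation. Its call was lost when any 1 of ChR2 wells 1, 3 and 5 or wild-type wells 1 and 3 was left out (adjusted p up to 0.0927). Pax7, the satellite cell factor, did not differ by more than the spread between wells (26.5 ± 3.60 against 21.4 ± 4.73 CPM, adjusted p = 0.186).

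Among 15 terminal myogenic regulators, 5 were lower in ChR2 wells. Myogenin (Myog), the factor that drives terminal differentiation, was at 542 ± 64.0 against 971 ± 233 CPM (log2 fold change -0.84, SE 0.17, adjusted p = 0.00219), and Cdkn1a, which encodes the cell cycle inhibitor p21, at 803 ± 99.6 against 1230 ± 209 CPM. Myod1 was at 153 ± 11.7 and 175 ± 33.9 CPM and was not called (adjusted p = 0.297). As a list they did not pass camera over all 12 libraries (adjusted p = 0.113) and passed without wild-type wells 2 and 5 (lower, adjusted p = 0.0271, or adjusted p = 0.626 with an estimated correlation), or without well 5 alone (0.0336). Of 14 fusion genes, 3 rose, among them Dock1 (1.21) and Stab2 (1.47), and 3 fell, among them Cav3 (-1.35) and Jam3 (-1.13). The fusion list did not pass camera (adjusted p = 0.959), whose direction was lower beside a median of 0.06 and a mean of 0.03.

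Contractile genes did not move as a block. Of 31 sarcomere scaffold genes, 11 were lower in ChR2 wells. Ttn, the giant spring protein titin, fell by 2.00 on the log2 scale over 12 libraries and by 0.79 without wild-type wells 2 and 5. Camera called the scaffold list lower (adjusted p = 0.0412, or adjusted p = 0.682 with an estimated correlation). Leaving out any 1 of ChR2 wells 3 and 4 or wild-type wells 2, 3, 4 and 6 ended that call (adjusted p up to 0.237). With wild-type wells 2 and 5 left out together, camera called the scaffold list lower (adjusted p = 0.00367, or adjusted p = 0.626 with an estimated correlation). In the excitation-contraction coupling list, 7 of 24 genes fell and 1 rose. The ryanodine receptor Ryr1 fell by 0.92 (0.60 without the same pair of wells) and the store-operated calcium channel Orai1 by 0.85, whereas triadin (Trdn) stood at 85.6 ± 18.6 CPM in ChR2 and 20.6 ± 18.3 CPM in wild-type wells. That list was called lower with adjusted p = 0.0486, or adjusted p = 0.748 with an estimated correlation. It lost its call without any 1 of ChR2 wells 1 to 4 or wild-type wells 2, 3, 4 and 6 (adjusted p up to 0.237). With wild-type wells 2 and 5 left out together, camera called it lower (adjusted p = 0.0179, or adjusted p = 0.731 with an estimated correlation).

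Of the myosin heavy chains, the slow and cardiac genes Myh7 and Myh6 were called higher over all 12 libraries. The adult fast genes Myh1, Myh2 and Myh4 had log2 fold changes of -0.22, 0.20 and 0.44 with adjusted p of 0.68, 0.749 and 0.591 (edgeR), and embryonic Myh3 one of 0.58 (adjusted p = 0.132, or 0.0232 without wild-type well 6). Slow Myh7 was at 542 ± 151 against 252 ± 161 CPM, a log2 fold change of 1.11 (adjusted p = 0.0422) that stood at 1.04 (adjusted p = 0.111) without wild-type wells 2 and 5. Its call was also lost without any 1 of ChR2 wells 1, 2, 3, 5 and 6 or wild-type wells 1, 3 and 5. Neonatal Myh8 had a log2 fold change of -0.96 (adjusted p = 0.0862), and -1.25 without that pair of wells (adjusted p = 0.0392), and it also passed without well 1 or well 5 alone (adjusted p down to 0.0227). Of 15 fast fibre genes 1 fell, Mybph (-0.65), and of 13 slow fibre genes 2 rose, Myh6 and Myh7, and 0 when adjusted over the list alone. Myh6 had a log2 fold change of 1.36 (adjusted p = 0.0324), and 1.16 (adjusted p = 0.0837) without wild-type wells 2 and 5, and its call was also lost without any 1 of ChR2 wells 1, 3, 5 and 6 or wild-type wells 1 and 3 (up to 0.0717). Without wild-type wells 2 and 5, 0 slow fibre genes were called higher and 2 lower, Casq2 (-0.46) and Myoz2 (-0.38), both named after their values were seen. Of 9 embryonic and neonatal genes, cardiac actin Actc1 (1.21) and smooth muscle actin Acta2 (0.71) rose and the myosin light chain Myl4 (-0.96) fell, and without that pair of wells 2 rose and 3 fell, Myl4, Myh8 and Chrna1. None of these 3 lists passed camera (adjusted p = 0.687, 0.652 and 0.652). The slow and embryonic lists had medians below 0 (-0.08 and -0.04) beside means above 0 (0.15 and 0.04), and for all 3 the direction of the test turned from higher to lower without that pair of wells.

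**Figure D2:**
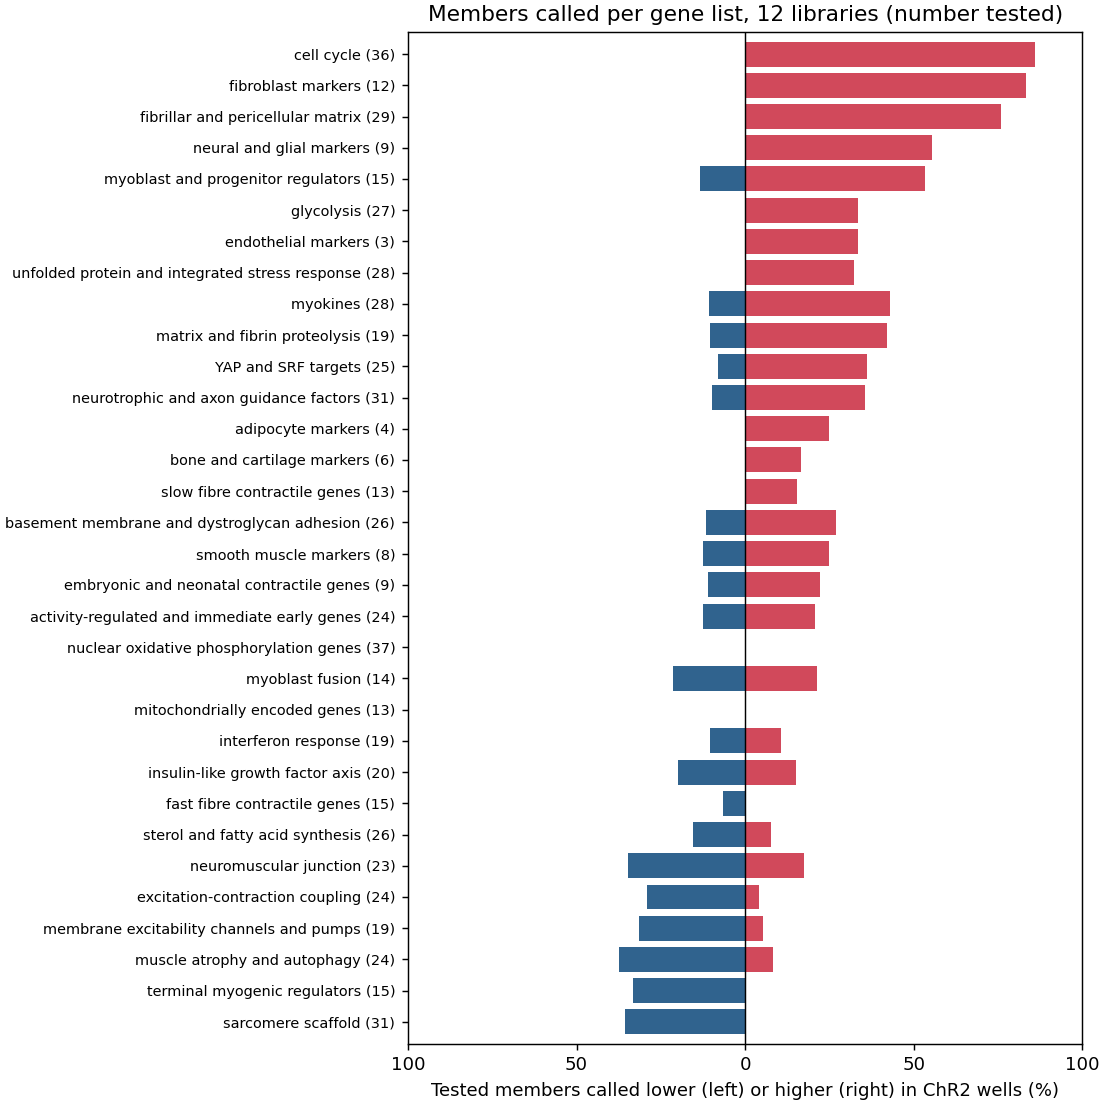
Share of tested members called higher (red, right) or lower (blue, left) in ChR2 wells, in percent, for each fixed gene list with at least 3 tested members except the RNAs without a poly(A) tail; the number tested is in brackets. Lists are ordered by the share higher minus the share lower, from cell cycle genes (31 of 36 higher) to sarcomere scaffold genes (11 of 31 lower).

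Genes of the neuromuscular junction moved both ways, 4 higher and 8 lower of 23. The muscle-specific kinase Musk, which organises the postsynaptic membrane, was at 53.7 ± 6.40 against 138 ± 40.9 CPM, and the neuregulin receptor Erbb3 at 49.6 ± 7.19 against 122 ± 20.5 CPM (log2 fold change -1.29, SE 0.14, adjusted p = 4.02e-05). Acetylcholinesterase (Ache) rose by 1.59 and neuregulin 1 (Nrg1) by 1.73 on the log2 scale. The acetylcholine receptor subunit Chrna1 was at 559 ± 19.3 and 590 ± 199 CPM and was not called (adjusted p = 0.795), but had a log2 fold change of -0.33 without wild-type wells 2 and 5 (adjusted p = 0.0174). Of 19 membrane channels and pumps, 1 rose, Trpc1 (10.7 ± 1.42 against 4.49 ± 1.5 CPM), and 6 fell, including the inward rectifier Kcnj12 (-1.70) and the sodium-calcium exchanger Slc8a1 (-1.54). Neither list passed camera over all 12 libraries (adjusted p = 0.108 and 0.0977). Without wild-type well 1 alone, both did with the preset correlation (adjusted p = 0.048 and 0.0258). Over all 12 libraries both had an adjusted p = 0.682 with an estimated correlation.

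Messages for secreted factors were higher in ChR2 wells for a part of each list. Among 28 myokines, 12 rose and 3 fell. The chemokine Cxcl12 was at 43.8 ± 11.5 against 7.60 ± 6.51 CPM and apelin (Apln) at 111 ± 15.4 against 25.2 ± 17.6 CPM, while Fndc5, the precursor of irisin, was at 28.5 ± 3.29 against 62.0 ± 8.81 CPM. Ccl2 fell by 2.67 over all libraries and by 0.82 without wild-type well 4, which alone held 33.1 CPM. Camera called the list higher (adjusted p = 0.0063, or adjusted p = 0.603 with an estimated correlation). Of 31 neurotrophic and axon guidance factors, 11 rose and 3 fell. Brain-derived neurotrophic factor (Bdnf) was at 18.1 ± 2.51 against 6.07 ± 1.40 CPM (log2 fold change 1.52, SE 0.16, adjusted p = 3.23e-05) and Igf1 at 5.95 ± 1.29 against 1.16 ± 1.22 CPM. Gdnf was not called over all libraries (log2 fold change 0.40, adjusted p = 0.247) and was without wild-type wells 2 and 5 (0.57, adjusted p = 0.0394). Sema4d fell by 0.96 and Efnb1 fell by 0.79. Without that pair of wells 15 rose and 4 fell. The neurotrophic list had an adjusted p of 0.039 by camera, an adjusted p = 0.258 with an estimated correlation, and an adjusted p of 0.0526 without wild-type well 3.

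Matrix genes rose broadly. Of 29 tested genes of the fibrillar and pericellular matrix, 22 were higher in ChR2 wells, with a median log2 fold change of 0.86. Fibromodulin (Fmod), which binds collagen fibrils, was at 8.11 ± 2.91 against 0.834 ± 0.565 CPM, and Col14a1 at 15.9 ± 3.06 against 2.96 ± 3.23 CPM. Camera gave an adjusted p = 4.77e-12, and an adjusted p = 0.258 with an estimated correlation. Fibroblast markers rose with them, 10 of 12 tested with a median log2 fold change of 0.92, and Mfap5 and Dcn are on both lists. Of 26 basement membrane and dystroglycan genes 7 rose, led by Col15a1 (2.70), and 3 fell. The list did not pass camera over all 12 libraries (adjusted p = 0.0977, or adjusted p = 0.682 with an estimated correlation). It passed without wild-type wells 2 and 5 together (adjusted p = 0.0147, or adjusted p = 0.626 with an estimated correlation) and without well 2 alone (adjusted p = 0.0333). In the list of matrix and fibrin proteolysis, 8 of 19 genes rose and 2 fell. The gelatinase Mmp2 was at 173 ± 24.7 against 50.7 ± 16 CPM and urokinase (Plau), which activates plasminogen, at 186 ± 17.7 against 108 ± 13.2 CPM, while cathepsin L (Ctsl) fell by 0.60. This list had an adjusted p of 0.0211, or an adjusted p = 0.603 with an estimated correlation. Of 25 YAP and SRF targets 9 rose, including Fhl2 (0.98) and Ccn1 (0.85), and 2 fell, including Amotl1 (-0.61), or 12 and 1 without wild-type wells 2 and 5. Their camera adjusted p was 0.0486, or adjusted p = 0.637 with an estimated correlation. The call was lost without any 1 of ChR2 wells 1, 3 and 4 or wild-type wells 1, 3, 4 and 6 (up to 0.171). With wild-type wells 2 and 5 left out together, camera called the list higher (adjusted p = 0.00367, or adjusted p = 0.602 with an estimated correlation).

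In the unfolded protein and integrated stress response list 9 of 28 genes rose, led by Trib3 (71.4 ± 6.69 against 26.6 ± 16.1 CPM) and Ddit3 (55.7 ± 8.99 against 18.3 ± 10.7 CPM), which lie downstream of Atf4. Its camera adjusted p was 0.0412, or adjusted p = 0.637 with an estimated correlation. The call was lost without wild-type wells 2 and 5 together (0.0674) and without any 1 of ChR2 well 4 or wild-type wells 1, 3 and 5 (up to 0.0922). Glycolysis genes rose for 9 of 27 tested identifiers, and in 17 without that pair of wells, with Aldoc at 12.8 ± 2.05 against 4.32 ± 2.21 CPM (camera adjusted p = 0.00539, or adjusted p = 0.637 with an estimated correlation). Of 24 atrophy and autophagy genes, 9 fell and 2 rose. The autophagy receptor Sqstm1 fell by 1.30 and the muscle ubiquitin ligase Trim63 by 1.02, whereas the mitophagy receptor Bnip3 rose by 0.83. That list was called lower (adjusted p = 0.0321, or adjusted p = 0.574 with an estimated correlation), and not without wild-type well 3 or well 4 (up to 0.071). Of 37 nuclear oxidative phosphorylation genes and 13 mitochondrially encoded genes, edgeR called 0, and 0 had an unadjusted p under 0.05; DESeq2 called 0 of either, and limma voom with quality weights called 0 and 1. Their camera adjusted p were 0.681 and 0.127. The second became 0.0462, in the direction of higher, without wild-type well 6. It had over all 12 libraries an adjusted p = 0.9 with an estimated correlation. Both tests turned from higher to lower without wild-type wells 2 and 5 (camera adjusted p = 0.695 and 0.342). The median log2 fold change of the mitochondrially encoded list went from 0.13 to -0.42 there. Of 26 sterol and fatty acid synthesis genes 2 rose and 4 fell, including Dhcr7 (-0.84), and the balance turned without wild-type wells 2 and 5, where 8 rose and 2 fell. Of 20 genes of the insulin-like growth factor axis 3 rose, including Igfbp3 (1.54), and 4 fell, including Igf2 (-0.68) and Grb10 (-1.26), against 4 and 2 without those wells. Neither of these last lists passed camera (adjusted p = 0.875 and 0.889). Both tests pointed lower over 12 libraries and higher without those wells (adjusted p = 0.851 and 0.702), beside 12-library values of a median of 0.0031 and a mean of -0.04 for the sterol list and a median of -0.13 and a mean of 0.11 for the growth factor list.

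Markers of other cell types were checked as fixed lists. Of 12 fibroblast markers 10 rose, among them Dpt (18.4 ± 2.95 against 2.41 ± 2.17 CPM) and Col15a1, and the list was called higher (camera adjusted p = 5.74e-05, or adjusted p = 0.258 with an estimated correlation). Of 9 tested neural and glial markers 5 rose, with the tubulin-binding Stmn2 at 131 ± 15 against 40.8 ± 11.1 CPM and Map2 at 21 ± 1.5 against 8.33 ± 2.30 CPM (camera adjusted p of the list = 0.0172, or adjusted p = 0.258 with an estimated correlation). Of 8 smooth muscle markers 2 rose, Smtn (1.09) and Acta2, and 1 fell, Des, whose log2 fold change of -0.63 (adjusted p = 0.0482) became -0.29 (adjusted p = 0.112) without wild-type wells 2 and 5 and was lost without any 1 library other than wild-type wells 1 and 4. The adipocyte, bone and cartilage, and endothelial lists had 1 called member each of 4, 6 and 3 tested, Pparg (0.72), Sox9 (0.52) and Flt1 (1.18), and camera called neither these nor the smooth muscle list (adjusted p = 0.985, 0.21, 0.6 and 0.652). The call of Sox9 was lost without any 1 of ChR2 well 3 or wild-type wells 1 and 3 (adjusted p up to 0.0615). Both tested immune markers, Cd14 (3.01 ± 0.63 against 4.4 ± 1.99 CPM) and Cd68 (4.09 ± 1.19 against 4.8 ± 2.4 CPM), were not called. Of 24 activity-regulated and immediate early genes 5 rose, including Klf4 (0.91) and Myc (0.66), and 3 fell, including Egr3 (-0.77), and of 19 interferon response genes 2 rose, B2m (0.87) and H2-D1 (0.60), and 2 fell, including Trim25 (-0.51). Those lists had camera adjusted p of 0.559 and 0.959. Of 21 RNAs without a poly(A) tail, 2 histone transcripts rose and 5 RNAs fell, with the levels in wild-type wells 2 and 5 given above (camera adjusted p = 0.391), and without those wells 6 of 22 rose and 0 fell, and the list was called higher (adjusted p = 0.0212, or adjusted p = 0.602 with an estimated correlation).

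**Figure D3:**
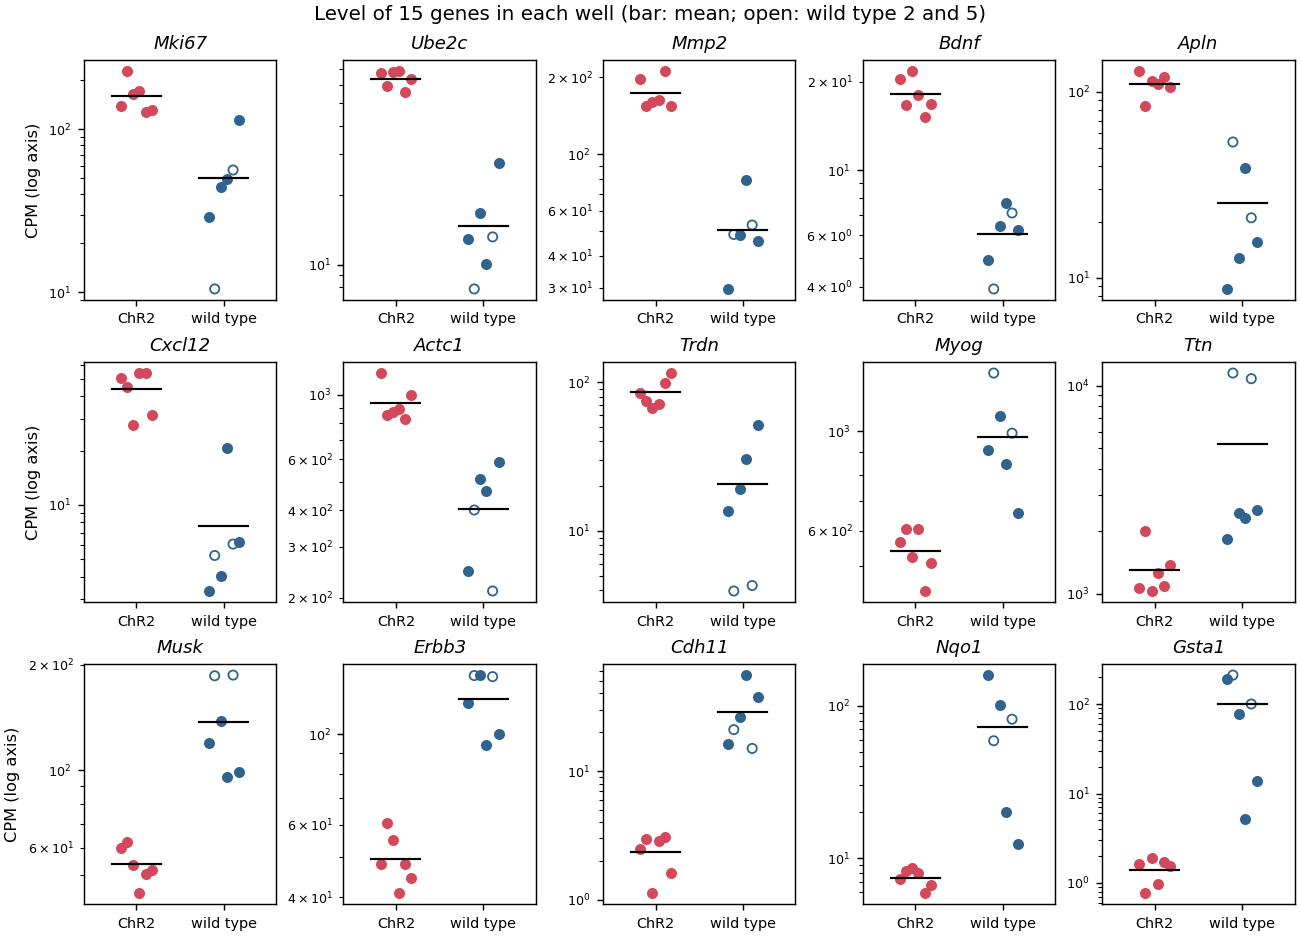
CPM on log axes of 15 genes in each well, ChR2 in red and wild type in blue, with wild-type wells 2 and 5 as open circles and a bar at the mean of each line. All 6 ChR2 wells lie above all wild-type wells for Bdnf, Cxcl12 and Trdn and below them for Musk, Erbb3 and Nqo1, while for Ttn the highest ChR2 well (2002 CPM) lies above wild-type well 1 only.

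Adjusted over the list alone, the counts were 32 higher of the cell cycle genes, 26 higher of the fibrillar matrix genes, 11 lower of the sarcomere scaffold genes, 12 higher and 3 lower of the myokines, and 11 higher and 3 lower of the neurotrophic factors. In all, camera called 14 of 33 tested lists with a preset correlation of 0.01, 11 higher and 3 lower, and 0 with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Fry, which asks whether the members of a list move one way on balance, called 12 higher and 1 lower.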

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

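The 3 tests of why wild-type wells 2 and 5 stand apart and the count over other divisions of the 10 libraries were chosen after the values were seen; the counts over other divisions of all 12 were planned. RNAs on the list without a poly(A) tail took 27.4% of the counts in wild-type well 2, far above the other wild-type wells (0.0264% to 9.57%). All 5 classes examined, 7SL, 7SK, Rpph1, Rmrp and the replication-dependent histones, took a larger share in both wells than in any of the other 10 libraries, which is consistent with preparation by ribosomal RNA depletion in place of poly(A) selection. The lower of the 2 wells' shares of the whole list was 101 times the highest of the other 10. No library is labelled as shallow or degraded RNA prepared by poly(A) selection. How far such RNA could raise these shares therefore stays open. The wild-type genotype is argued against, since 4 of the other 4 wild-type libraries lay below the highest ChR2 library. No label says how either library was made, so depletion remains a hypothesis.

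ChR2 well 4 differed from the other ChR2 wells in RNAs without a poly(A) tail and in ribosomal RNA. The list without a poly(A) tail took 0.0945% there and at most 0.0473% in the others, the 18S ribosomal repeat 3.77% against at most 0.693%, and Rpph1 stood at 17.3 CPM against at most 1.86 CPM. In the 18S share, wild-type wells 2 and 5 went the other way. At 0.215% and 0.125% they were the lowest of the 12 libraries, with 0.216% in wild-type well 6.

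Single wells lay far from the rest of their line for 26 of 252 combinations of a named gene and a line, where chance gives about 1 in 20, or 12.6, and for 3 of 12 combinations of a library measure and a line, where chance gives 0.6. Of the 18 in the wild-type line, 12 were in well 2 or 5. In well 2, Rn7s1 stood at 84877 CPM, Des at 5717 CPM, Myl4 at 1468 CPM, Ryr1 at 1274 CPM, Trim63 at 157 CPM, Gstp2 at 101 CPM and Flt1 at 6.55 CPM, all above the other wild-type wells, and Ccn1 at 24.9 CPM, Map2 at 3.93 CPM and H2bc21 at 1.31 CPM, all below them. The floor of detection, a count of 3, is 3.93 CPM in well 2, so Map2 lay at it there, H2bc21 below it and Flt1 little above it. In well 5, Sox9 was high at 77.4 CPM and Rab29 low at 3.57 CPM. In well 6, H2ac24 (111 CPM), Id3 (61.9 CPM), Ccnb2 (23.0 CPM) and Igf1 (3.45 CPM) were high, and in well 4, Ccl2 (33.1 CPM) and Cxcl12 (20.7 CPM).

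In the ChR2 line, well 2 was high for Ttn (2002 CPM), Pde3a (8.37 CPM) and Fosb (1.87 CPM) and low for Slc8a1 (9.47 CPM). Well 3 was low for the minor Aldoa identifier (0.755 CPM), and well 4 was high for Flt1 (7.14 CPM).

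Other divisions of the 12 libraries into groups of 6 were fitted in the same way, 100 in all with the real one. Only 1 of the 100, the real one, gave 3701 changed genes, and the highest other gave 1 gene. The same held for the 1838 higher, the 1863 lower and the 956 genes changed at least 2-fold, again with 1 of 100 and a highest other count of 1, and for the 4749 genes changed in the 10 libraries. A chance division of these wells is thus an unlikely source of these counts. The comparison says nothing of chance differences between cultures, since no label says that the wells of a line came from separate cultures. Every other division mixes the lines and so carries their difference into the spread within groups, which lowers its counts. Those low counts are therefore no measure of false calls in the real division. For the number of gene lists called, 13 of the 100 divisions gave 14 or more, and the highest other gave 18, so chance is not excluded for that number.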

How the results depend on the processing

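Of 126 named genes, 109 kept their side of the threshold in each fit that left 1 library out, and 41 in each other alternative. Some of the uncalled genes among them changed sign, such as Myh1 and Atp5b. Without any 1 library, 2822 to 4115 genes changed, 1497 to 2120 higher and 1284 to 2127 lower, with 900 to 1185 changed at least 2-fold, and 7 to 14 lists were called, 7 without wild-type well 3. The planned filter of 1 CPM in 6 libraries removed no tested gene and tests nothing. Depth limits what wild-type wells 2 and 5 (1061050 and 2809670 counts) show for low genes.

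On log2(TPM + 1) 607 genes changed, 578 higher (95.2%, against 49.7% on counts), 29 lower and 547 at least 2-fold. On log2(TPM + 0.1) it was 257, with 240 higher, 17 lower and 257 at least 2-fold. On log2(TPM + 1) with no filter it was 458, with 432 higher, 26 lower and 304 at least 2-fold. TPM moved the median log2 fold change of the filtered genes to 0.35 and 0.43; TPM sums to a fixed total that RNAs without a poly(A) tail fill in wild-type wells 2 and 5. On log2(TPM + 1) in the 10 libraries, chosen after the data were seen, 3421 changed, 1547 higher (45.2%), 1874 lower and 511 at least 2-fold. Against a 1.5-fold change 555 were called, 413 higher and 142 lower, by the construction of that test. Voom with quality weights gave 2810 higher genes of 5462, and at least 5 CPM left 628 genes changed 2-fold with fewer genes tested. For voom the cause was not tested.

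With the replicate number as a block, 2641 genes changed, 1171 of them lower and 1470 higher, and 12 lists were called. Same-numbered wells correlated between -0.14 and 0.095 in their deviations from the line means, and 1 of 6 matched its own number best. No clear pairing by number was seen. The check included the wild-type wells that stood apart, whose large deviations may hide a weak pairing. It therefore cannot decide whether same-numbered wells share more than a number.

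With an estimated correlation, 0 lists were called, against 14, since a higher correlation between members widens the test. The remaining alternatives were chosen after the data were seen. The list of RNAs without a poly(A) tail turned from lower, not called, to higher: adjusted p 0.0212 in 10 libraries, 0.0397 in 9 and 0.00978 with a covariate for wild-type wells 2 and 5. Rn7s1 turned to 0.90, 0.12 and 0.88 on the log2 scale, Rpph1 to 1.83, 0.0121 and 1.75, and 0.44 on TPM in 10 libraries, all uncalled. Of 111 named genes called, 100 were called again in 10 libraries. Among those that were not were Des, Fosb, Gbp2, H2ac24, Id3, Lats2, Myh6 and Myh7.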

Other observations

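All tests in this part were chosen after the results were seen, except the median of long transcripts, whose comparison with the spread was added afterwards. A list of 34 targets of NRF2, the transcription factor of the oxidative stress response, was written after Nqo1, Gsta1 and others had been seen among the largest falls, and the genes named here were chosen after their values were seen. Of 31 tested, 18 were lower and 3 higher in ChR2 wells. Heme oxygenase Hmox1 was at 37.5 ± 4.36 against 193 ± 139 CPM, the glutathione synthesis gene Gclm at 20.3 ± 2.81 against 66.3 ± 45.1 CPM, and the ferritin gene Fth1 fell by 0.84 on the log2 scale, while Ugdh rose by 0.82. Camera gave p = 8.77e-05 with a preset and p = 0.279 with an estimated correlation; 1 member is also in a fixed list.

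The wild-type wells were unlike each other in these genes. The mean log2 level of the 31 members, relative to the ChR2 mean, was 1.42, 0.92, 1.10, 0.17, 1.54 and -0.08 in wild-type wells 1 to 6, and between -0.12 and 0.06 in the ChR2 wells. The pair of atypical libraries does not carry the difference, since 14 targets were called lower without them, nor do reads shared between glutathione S-transferase paralogs, since 11 of those 14 lie outside that family. A condition of single wild-type wells may account for the size: the smallest shift was -0.0493 of the largest, and the median log2 ratio of the lowest wild-type to the highest ChR2 well among the 14 genes was -0.0271. For the direction, 5 of 6 wild-type wells lay above every ChR2 well, which leaves it open. A difference between the lines themselves was not tested and also stays open.

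Called higher were 31 of 36 cell cycle genes, 22 of 29 matrix genes and 10 of 12 fibroblast markers, some of them also matrix genes (adjusted p = 0.258 for each list with an estimated correlation), and called lower were 11 of 31 sarcomere scaffold genes (adjusted p = 0.682 with an estimated correlation, and with a preset one up to 0.237 without any 1 of 6 libraries). The atypical wild-type libraries do not account for the cell cycle, matrix and scaffold calls. Of the 64 calls in those lists, 98.4% were kept without them, though Des was lost and Ttn shrank from -2.00 to -0.79. The fibroblast marker calls were not followed in this way. Camera called the scaffold list lower without those libraries (adjusted p = 0.00367, or adjusted p = 0.626 with an estimated correlation). Without those libraries, 10 of 13 tested fibroblast markers were called higher and 1 lower. Whether a smaller share of myotubes alone accounts for the scaffold falls could not be decided. That cause would lower genes made only by myotubes by 1 common amount. The 87 genes tested in the 10 libraries were not limited to such genes. Of them 25 were called lower and 3 higher (Actc1, Trdn and Acta2, the last also made by unfused cells). Around a median log2 fold change of -0.21 their interquartile range, 0.515, exceeded 2 median standard errors, 0.375. For loss of long transcripts, the 644 longest genes outside the lists had a median log2 fold change of -0.0554 in the 10 libraries. By the limits set beforehand, that median lay on the side of no general loss. Single genes spread widely around it (interquartile range 0.621), and the median over 12 libraries was -0.16. Such a loss therefore stays open for single scaffold genes. A larger share of unfused, dividing cells or of fibroblast-like cells also stays open, as does an untested difference between the lines: of the lists outside this pattern, progenitor and terminal regulators, 2 of 2 passed camera in the predicted direction in the 10 libraries with a preset correlation and 0 with an estimated one (adjusted p = 0.626 for both), and over 12 libraries the terminal regulators did not pass (0.113).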
